A study of Drosophila melanogaster with 30 samples.

How the data were processed

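Cells isolated from the brains of wandering L3 larvae of Drosophila melanogaster were profiled by micrococcal nuclease (MNase) ChIP-seq for trimethylated histone H3 lysine 4 (H3K4me3), a mark of active gene starts, and trimethylated lysine 27 (H3K27me3), the mark placed by Polycomb repressive complex PRC2. For each mark there were 4 groups of 2 libraries: type I neuroblasts, neuroblasts with brat RNAi, neuroblasts with brat and numb RNAi, and neurons. The 14 input samples of the series were not analysed here.

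The deposited values are each a count, a whole number of reads per gene and library with no normalization, 1 line per gene for 14284 genes. H3K4me3 reads were counted in the 501 bases from the start of each gene, and H3K27me3 reads over the whole gene model (median length 2029 bases). Each gene has 1 H3K4me3 window, at the outer end of its gene model. H3K4me3 at any further start within a gene was therefore not measured, and a low value need not hold for the whole gene. The submitters' processing notes name the genome build dm3 and the tools Bowtie2 2.2.4, deepTools 2.5.0.1 and bedtools 2.25.0; counting settings and the handling of duplicate reads are not stated. No input was subtracted from the counts. Positions are those of the deposited tables. Gene names were matched through symbols and synonyms of a later annotation release, from which no coordinates were taken. A window can overlap that of another gene: this holds for 772 of the genes tested for H3K4me3 and 5382 of those tested for H3K27me3, so their reads are shared.

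Counts were fitted in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, robust), TMM scaling and the default low-count filter by group, which left 14185 genes for H3K4me3 and 14182 for H3K27me3. All 8 libraries of a mark were in the fit, with group means only, which leaves 4 residual degrees of freedom. The 4 comparisons per mark were neurons, brat RNAi and brat numb RNAi against type I neuroblasts, and brat numb RNAi against brat RNAi. P values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels are TMM-scaled CPM (edgeR's cpm function), given as mean ± SD over 2 libraries, and log2 fold changes are given with a standard error (SE). This SE was derived from the edgeR test, as the absolute log2 fold change divided by the square root of F. P values measure only the spread between these samples, since nothing states that the 2 libraries of a group come from separate animals. Because edgeR moderates the spread of a gene toward that of genes of like abundance, p values do not measure its own spread alone. For the H3K4me3 genes named, p values of this fit match a normal distribution of log2 fold change over SE. The spread of a single gene between its libraries thus had next to no weight in them. For H3K4me3 in neurons against type I neuroblasts the SE was 0.7165 at dpn and 0.7166 at wor. The SD of the type I libraries at these genes was 89.6 and 19.9 CPM. The 4 residual degrees of freedom are those before this sharing. Total counts were 2461222 to 12258131 per library for H3K4me3 and 15281722 to 25009648 for H3K27me3.

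The 19 gene lists were fixed before the data were examined, as were the fit, the comparisons and the settings varied, except where the text says otherwise. They are neuroblast identity, temporal patterning, type II lineage and intermediate progenitors, Notch pathway and E(spl) complex, neuronal function, neuronal differentiation factors, cell cycle and DNA replication, growth and ribosome biogenesis, Hox genes, Polycomb target developmental transcription factors, Polycomb and Trithorax group members, apoptosis genes of the H99 region, and markers or genes of glia, hemocytes and fat body, muscle, germline, glycolysis, oxidative phosphorylation, and heat shock and stress response. Of 406 list entries 403 were matched. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison and mark, and again with an estimated correlation. Overlaps of calls were tested with 1-sided Fisher's exact tests, which take genes as independent. Neighbouring genes that change together are not, so these p values can be too small.

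The rule for named genes took brat and numb in every comparison, the 5 largest rises and the 5 largest falls among genes past the threshold whose abundance was above the median and whose libraries did not overlap between groups, and up to 4 members past the threshold from each list. Up to 2 members that did not pass are named with their values for a list with fewer than 2 that passed. Other genes were chosen after their values were seen and are said to be so. This also holds for Cyp6a17 and, outside the H3K4me3 comparison of brat RNAi with type I neuroblasts, for asparagine-synthetase.

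The labels carry SBa codes whose meaning is not stated. They were treated as a possible batch: H3K4me3 libraries carry codes 27, 51, 67 and 68, and H3K27me3 libraries 26, 34, 51, 67 and 68. Groups that share a code were also compared within it, and for H3K4me3 the code was added to the fit as a block, which leaves 1 residual degree of freedom. That degree of freedom comes only from the type I and neuron libraries of codes 27 and 51. It too is counted before the spread is shared between genes, so small p values of the block do not measure a gene's own spread. With this block, brat RNAi against type I neuroblasts rests on brat RNAi replicate 1. Brat numb RNAi against brat RNAi rests on 1 library of each, in code 68, and brat numb RNAi is linked to type I neuroblasts only through brat RNAi. Calls of the block in these comparisons thus have no replication of the RNAi groups. For H3K27me3 such a fit has no residual degrees of freedom. The replicate numbers in the titles were used; for the brat RNAi libraries those in the file labels differ. Alternatives were DESeq2 1.42.0 size factors, scaling by library totals, offsets that remove a trend with abundance (cyclic loess, 3 iterations, 0.5 added to counts), no low-count filter, the DESeq2 test, a fit of only the 2 groups compared, the replicate number as a block, and each library left out in turn. The pipeline was tested on simulated data in which 200 genes were changed by known folds.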

Results

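The 16 libraries profiled 2 histone marks in 4 kinds of larval brain cells, with 2 libraries per group and mark. Type I neuroblasts are neural stem cells that divide into a further neuroblast and a ganglion mother cell. Brat is a translational repressor of the TRIM-NHL family that limits self-renewal in the type II neuroblast lineages, and Numb is an inhibitor of Notch signalling; RNAi against them gives the neuroblasts that the series title calls tumorigenic. The H3K4me3 libraries of type I neuroblasts held 10379268 and 12258131 reads, those of brat RNAi 10707815 and 2461222, those of brat numb RNAi 3660892 and 11141538 and those of neurons 9391818 and 5407777. The H3K27me3 libraries held 15306647 and 15281722, 16868854 and 19045164, 16508148 and 18429668, and 16702071 and 25009648 reads in the same order of groups.

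Libraries of a group were not always closer to each other than to other groups. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.901 to 0.961 within groups and 0.842 to 0.985 between groups for H3K4me3, and at 0.928 to 0.99 and 0.848 to 0.986 for H3K27me3. Chi-square per degree of freedom between the libraries of a group was 10.1 to 269, so no library was a copy of another of its group. Chromosome 4 stood apart in the H3K4me3 libraries of SBa code 27: the median log2 CPM of its 85 genes, less that of chromosomes 2 and 3, was 3.22 in type I neuroblasts, 0.96 in brat RNAi and 3.43 in neurons, against -0.53 to 0.04 in the other 5 libraries. With TMM scaling the median H3K4me3 log2 fold change of all genes was 0.24 for neurons, -0.02 for brat RNAi and 0.27 for brat numb RNAi against type I neuroblasts, and 0.01 for brat numb RNAi against brat RNAi. With library totals these medians were 0.61, 0.39, 0.83 and 0.11, and with DESeq2 size factors 0.10, -0.09, 0.05 and -0.12. For H3K27me3 the medians were 0.08, -0.01, -0.02 and 0 with TMM and 0.08, -0.15, 0.17 and 0.33 with library totals.

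The RNAi targets carried both marks at similar levels in the neuroblast groups; reads from histone marks do not measure the knockdown. H3K4me3 at the start of brat (FBgn0010300, 2L: 19133806 to 19134306) was 327 ± 104 CPM in type I neuroblasts, 223 ± 4.93 in brat RNAi, 197 ± 66.5 in brat numb RNAi and 290 ± 124 in neurons (SD, n = 2). At numb (FBgn0002973, 2L: 9437469 to 9437969) it was 18.9 ± 12.2, 28.4 ± 17, 17.9 ± 1.36 and 72 ± 2.81 CPM in the same order. H3K27me3 over brat was 189 ± 11.5, 176 ± 56.3, 159 ± 27.1 and 268 ± 68.5 CPM, and over numb 153 ± 4.41, 141 ± 26.9, 138 ± 14.6 and 243 ± 43 CPM. Neither gene passed edgeR's quasi-likelihood test of all 8 libraries in any of the 8 comparisons; the lowest adjusted p was 0.28, for H3K4me3 at numb in neurons against type I neuroblasts (log2 fold change 1.93, SE 0.72), which passed in a fit of those groups alone (adjusted p = 0.044) and with the SBa code as a block (adjusted p = 9.3e-05, 1 residual degree of freedom). In SBa codes 27 and 51 that log2 ratio at numb was 1.42 and 2.73.

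Neurons were compared with type I neuroblasts to ask how the marks differ between stem cells and their differentiated progeny. H3K4me3 fell in neurons at the starts of 3 neuroblast transcription factor and polarity genes and of 4 cell cycle and DNA replication genes. At dpn, a neuroblast self-renewal repressor of the Hes family (FBgn0010109, 2R: 4119332 to 4119832), it was 183 ± 89.6 CPM in type I neuroblasts and 23.2 ± 2.69 in neurons (SD, n = 2; log2 fold change -2.97, SE 0.72, adjusted p = 0.021, edgeR). The Snail family gene wor (FBgn0001983, 2L: 15425085 to 15425585) fell from 185 ± 19.9 to 24.2 ± 0.236 CPM (log2 fold change -2.93, SE 0.72, adjusted p = 0.025). The gene mira, which encodes the adaptor that segregates fate determinants (FBgn0021776, 3R: 15760342 to 15760842), fell from 147 ± 70.8 to 21.4 ± 1.71 CPM (log2 fold change -2.77, SE 0.71, adjusted p = 0.033). Cyclin E (CycE, FBgn0010382, 2L: 15747655 to 15748155) fell from 196 ± 16.2 to 19.5 ± 9 CPM (log2 fold change -3.33, SE 0.73, adjusted p = 0.0072). The replication licensing genes Cdc6 (FBgn0035918, 3L: 8626681 to 8627181), Mcm2 (FBgn0014861, 3R: 4090565 to 4091065) and Orc1 (FBgn0022772, 2R: 3412713 to 3413213) fell by log2 fold changes of -2.96 ± 0.71, -2.72 ± 0.71 and -2.71 ± 0.71 (SE), with adjusted p of 0.021, 0.035 and 0.036.

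All 36 measured genes of cell cycle and DNA replication had lower mean H3K4me3 in neurons, with a median log2 fold change of -1.78. Of them 4 passed over all genes, 25 adjusted over the list alone and 27 at an unadjusted p under 0.05, and the list fell (adjusted p = 8.2e-28). With an estimated correlation it did not pass (adjusted p = 0.79). In neuroblast identity 3 of 17 fell over all genes, and adjusted over the list alone 8 fell and 1 rose. The list fell (adjusted p = 0.00079). Its adjusted p was 0.79 with an estimated correlation. Growth and ribosome biogenesis fell as a list with no member past the threshold in edgeR's fit of all libraries or DESeq2 and 4 of 20 lower at an unadjusted p under 0.05 (adjusted p = 1.4e-05). This call was lost with an estimated correlation (adjusted p = 0.79). The gene nop5 was at -1.93 ± 0.69 and Nop60B at -1.65 ± 0.68 (log2 fold change ± SE). Both passed in edgeR's fit of these groups alone (adjusted p = 0.0049 and 0.025) and with the SBa code block (adjusted p = 1.3e-08 and 1.8e-06). Neuronal function rose as a list (adjusted p = 1.4e-07), with 37 of 39 members higher. The list had adjusted p = 0.79 with an estimated correlation. None of its members passed the threshold in edgeR's fit of all libraries, with 8 higher and 1 lower at an unadjusted p under 0.05, and 1 lower by DESeq2. With the SBa code as a block, which leaves 1 residual degree of freedom, 25 members were called higher and 1 lower. That block called 32 of 36 cell cycle genes and 14 of 20 growth genes lower and 0 higher, and 3 higher and 8 lower in neuroblast identity. The neuronal function genes Lcch3, a GABA receptor subunit, and Syt1, the synaptic calcium sensor, were at 2.05 ± 0.70 and 1.57 ± 0.69 (adjusted p = 4.1e-06 and 5.9e-05 with the code block); the type I libraries of Syt1 varied widely (38 ± 41.1 CPM). The other 15 lists did not pass for this mark; adjusted over the list alone, 1 type II lineage gene was higher and 1 lower, and 1 germline gene was lower.

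The largest fall past the threshold was at CG16879 (FBgn0028904, 2L: 14104483 to 14104983; 124 ± 3.94 to 6.25 ± 2.66 CPM; log2 fold change -4.31, SE 0.77, adjusted p = 0.00031). Next came CR43650 (FBgn0263659, 2R: 12716605 to 12717105; log2 fold change -4.005, SE 0.75, adjusted p = 0.00065) and CR31386 (FBgn0051386, 3R: 7130830 to 7131330; log2 fold change -3.97, SE 0.75, adjusted p = 0.00065). They were followed by CG15047 (FBgn0030938, X: 18422722 to 18423222; log2 fold change -3.96, SE 0.76, adjusted p = 0.00065) and PsGEF (FBgn0040387, X: 2281197 to 2281697; log2 fold change -3.88, SE 0.75, adjusted p = 0.00065). The gene that rose past the threshold was CG34377 (FBgn0263117, 3R: 18149316 to 18149816), from 7.47 ± 0.767 to 64 ± 37.6 CPM (log2 fold change 3.10, SE 0.79, adjusted p = 0.033). In all, edgeR's quasi-likelihood test called 1 gene higher and 63 lower of 14185 (1025 at an unadjusted p under 0.05), and DESeq2 called 13 higher and 363 lower. All 64 also passed with the SBa code as a block, a fit with 1 residual degree of freedom that called 2313 higher and 2298 lower. Of the 64 genes, the fit of these groups alone and DESeq2 also called 64, library totals 60, abundance-trend offsets 35 and DESeq2 size factors 18. Within codes 27 and 51, the log2 ratios of neurons to type I neuroblasts correlated across genes at r = 0.73 (Spearman's rho 0.71), and at -0.02 when the codes were crossed; dpn was at -3.28 and -2.47, CycE at -3.79 and -2.99. With library totals the split was 99 higher and 373 lower. The count was 33 (22 higher, 11 lower) without type I replicate 1, 2 (0 higher, 2 lower) without type I replicate 2, 11 (0 higher, 11 lower) without brat RNAi replicate 1, 248 (6 higher, 242 lower) without brat RNAi replicate 2, 400 (23 higher, 377 lower) without brat numb RNAi replicate 1, 291 (16 higher, 275 lower) without brat numb RNAi replicate 2, 10 (0 higher, 10 lower) without neuron replicate 1 and 149 (4 higher, 145 lower) without neuron replicate 2. Most calls without type I replicate 1 were thus rises, and 11 of those 33 genes were among the 64.

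**Figure D1:**
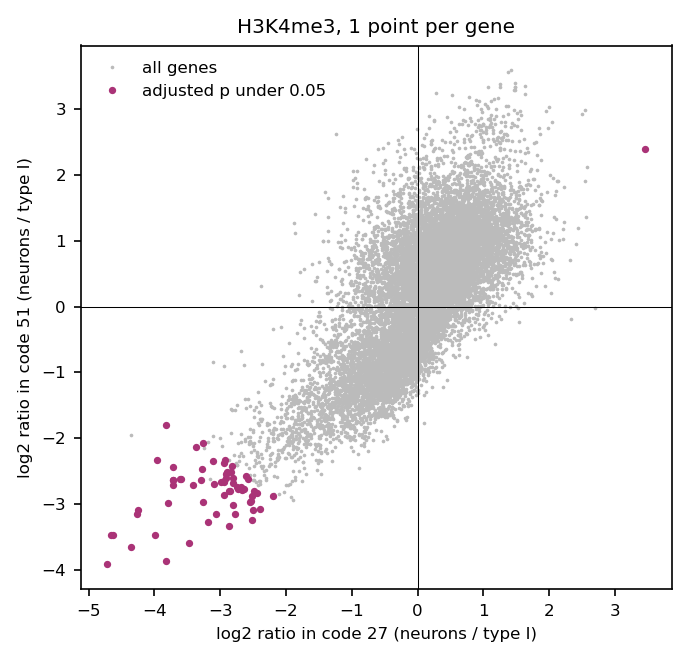
H3K4me3 log2 ratio of neurons to type I neuroblasts, 1 point per gene, between the libraries of SBa code 27 (horizontal axis) and of code 51 (vertical axis); coloured points are the 64 genes past the edgeR threshold. The ratios correlate at r = 0.73 across genes.

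H3K27me3 passed edgeR's threshold at no gene between neurons and type I neuroblasts (1277 of 14182 at an unadjusted p under 0.05; smallest adjusted p = 0.53), while DESeq2 called 43 higher and 9 lower and edgeR's fit of these groups alone 7 higher and 4 lower. At the Grainyhead gene grh (FBgn0259211, 2R: 13690294 to 13729584), a late neuroblast factor, it was 165 ± 16.7 CPM in type I neuroblasts and 863 ± 580 in neurons (SD, n = 2; log2 fold change 2.39, SE 0.50; DESeq2 adjusted p = 0.0019). At cas, a temporal factor (FBgn0004878, 3R: 1538664 to 1543022), it was 112 ± 32.4 and 31.7 ± 3.11 CPM (log2 fold change -1.83, SE 0.43; DESeq2 adjusted p = 0.03). The chromosome 4 zinc finger genes Lin29 and zfh2 were at 1325 ± 1209 and 1481 ± 1153 CPM in neurons and 97.1 ± 4.49 and 261 ± 51.2 in type I neuroblasts. Over all 84 chromosome 4 genes the median log2 fold change was 0.84 above that of chromosomes 2 and 3. The hemocyte gene Hml was at 402 ± 96.8 and 144 ± 29.5 CPM (log2 fold change -1.48, SE 0.27; DESeq2 adjusted p = 0.019). In the fit of these groups alone edgeR called cas and Hml (adjusted p = 0.037 for each) but not grh (adjusted p = 0.14). Within SBa code 26, the log2 ratio was 3.06 at grh, -1.99 at cas and -1.51 at Hml.

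As lists, H3K27me3 rose in neurons over Polycomb and Trithorax group members (adjusted p = 0.0024), neuroblast identity (adjusted p = 0.011) and neuronal differentiation factors (adjusted p = 0.011). These 3 lists had adjusted p of 0.9 with an estimated correlation. It also rose over Notch pathway and E(spl) complex (adjusted p = 0.031) and apoptosis genes of the H99 region (adjusted p = 0.043), and fell over hemocyte and fat body markers (adjusted p = 0.011). None of these 3 lists passed with an estimated correlation (adjusted p = 0.9). Adjusted over the list alone, neuroblast identity and neuronal differentiation factors each had 2 members higher and 1 lower, the H99 region 1 higher, and hemocyte markers 1 lower. The calls of Notch pathway and H99 genes ended with offsets that remove the abundance trend (adjusted p = 0.08 and 0.061). The 13 other lists did not pass, and of their members 1 temporal patterning gene was lower adjusted over the list alone. In neuronal function futsch and Rab3 were at -0.93 ± 0.27 and -0.75 ± 0.24 (log2 fold change ± SE), and in temporal patterning mamo and svp at -1.08 ± 0.23 and 1.77 ± 0.58. The neuron libraries lay far apart at several of these genes, and without neuron replicate 2 edgeR called 130 genes higher.

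Whether a gene that lost H3K4me3 gained H3K27me3 could not be read from the edgeR calls, since none were made for H3K27me3. With DESeq2, 9 of the genes lower in H3K4me3 in neurons were higher in H3K27me3, where 1.1 were expected by chance (1-sided Fisher's exact p = 1.1e-06): aos, Arr2, CG10195, CG13305, CG16879, CG6486, CG9238, CR31386 and CR43283, named after their values were seen. In simulated data DESeq2 made 31 calls among unchanged genes for H3K4me3 and 42 for H3K27me3, against 2 and 8 by edgeR, so part of the calls made by DESeq2 alone, here and below, can be false. CR31386 (3R: 7095137 to 7131330) and CR43283 (3R: 7073825 to 7081845) lie near each other, and Fisher's test counts them as independent. At CR31386, H3K27me3 was 208 ± 14.6 CPM in type I neuroblasts and 2611 ± 2532 in neurons. No gene was called by DESeq2 as higher in H3K4me3 and lower in H3K27me3. The log2 fold changes of the marks correlated at r = -0.26 across genes, and at 0.04 with abundance-trend offsets. This r was 0.04 without type I replicate 1, -0.40 without type I replicate 2, -0.50 without neuron replicate 1 and 0.00 without neuron replicate 2.

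The brat RNAi neuroblasts were compared with type I neuroblasts to see which chromatin differs in tumour-forming cells. No group held normal type II neuroblasts. A difference between tumour-forming and normal cells therefore cannot be told apart from a difference between type I and type II lineages. H3K4me3 rose most at Gadd45, a stress-inducible gene (FBgn0033153, 2R: 3136668 to 3137168), from 8.14 ± 1.55 CPM in type I neuroblasts to 236 ± 55.1 in brat RNAi (SD, n = 2; log2 fold change 4.85, SE 0.78, adjusted p = 8.1e-06, edgeR quasi-likelihood). It rose at the glutathione transferase gene GstE6 (FBgn0063494, 2R: 14293518 to 14294018; log2 fold change 3.91, SE 0.76, adjusted p = 0.0017) and at CG11263 (FBgn0036330, 3L: 12999924 to 13000424; log2 fold change 3.32, SE 0.74, adjusted p = 0.02). It rose at ImpL3, which encodes lactate dehydrogenase (FBgn0001258, 3L: 6255293 to 6255793; 9.96 ± 1.15 to 86.4 ± 26.3 CPM; log2 fold change 3.12, SE 0.74, adjusted p = 0.04). The last of the 5 was asparagine-synthetase (FBgn0041607, 3L: 21166218 to 21166718; log2 fold change 3.05, SE 0.72, adjusted p = 0.04), whose window overlaps that of chb. It fell at ase, the proneural gene that marks type I neuroblasts and is absent from type II (FBgn0000137, X: 354533 to 355033), from 168 ± 16.8 to 21.2 ± 18.1 CPM (log2 fold change -3.01, SE 0.72, adjusted p = 0.04). It also fell at the zinc finger gene scrt (FBgn0004880, 3L: 3983916 to 3984416; log2 fold change -3.45, SE 0.75, adjusted p = 0.014) and at oc, the orthodenticle homeobox gene (FBgn0004102, X: 8544214 to 8544714; log2 fold change -3.28, SE 0.81, adjusted p = 0.049). A further large fall was at CG34420 (FBgn0085449, 3L: 11856047 to 11856547; 16.8 ± 14.3 to 0.963 ± 1.36 CPM; log2 fold change -3.82, SE 0.87, adjusted p = 0.027). Others were at CG30419 (FBgn0050419, 2R: 20116811 to 20117311; log2 fold change -3.82, SE 0.80, adjusted p = 0.0077) and CG10362 (FBgn0030358, X: 11824383 to 11824883; log2 fold change -3.20, SE 0.75, adjusted p = 0.039).

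These are 6 genes higher and 8 lower of 14185 (783 at an unadjusted p under 0.05); the others were chb, CG31688 and CG3955 (log2 fold changes 2.96 ± 0.73, -3.05 ± 0.74 and -3.07 ± 0.75, SE), named after their values were seen. At 5 of the 8 genes that fell the type I libraries stood apart, replicate 1 above replicate 2, and the mean of neurons lay above both. The levels in the type I libraries, in the order of replicates, were 78.4 and 31.8 CPM at scrt, 70 and 18 at CG10362, 26.9 and 6.75 at CG34420, 103 and 16.4 at CG31688 and 76.9 and 15.1 at CG3955. In neurons they were 136 ± 48, 127 ± 17.3, 49.4 ± 3.37, 124 ± 28.1 and 103 ± 44.9 CPM. DESeq2 called 48 higher and 72 lower. With the SBa code as a block, brat RNAi rests on replicate 1 alone, and the log2 fold change was 5.46 at Gadd45 and -4.32 at ase. Within SBa code 27, the log2 ratio of brat RNAi to type I was 5.24 at Gadd45, 3.25 at ImpL3, -4.17 at ase and -3.68 at oc. Abundance-trend offsets left 2 higher and 0 lower, DESeq2 size factors gave 11 and 12, library totals 12 and 33, and the fit of these groups alone 13 and 6. Of the 14 genes, DESeq2 also called 13, DESeq2 size factors 11, library totals 8, the fit of these groups alone 7 and abundance-trend offsets 2. The fit of these groups alone kept ase (adjusted p = 0.00018) and lost CG30419, CG34420, CG31688, CG3955, CG10362, scrt and oc (adjusted p = 0.059 to 0.31). The count was 0 without type I replicate 1, 28 (3 higher, 25 lower) without type I replicate 2, 2 (2 higher, 0 lower) without brat RNAi replicate 1, 4 (3 higher, 1 lower) without brat RNAi replicate 2, 33 (11 higher, 22 lower) without brat numb RNAi replicate 1 and 53 (14 higher, 39 lower) without brat numb RNAi replicate 2.

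Among the lists, H3K4me3 fell in brat RNAi over neuroblast identity, where ase and scrt passed over all genes and adjusted over the list alone (adjusted p = 0.0049). This call was lost with an estimated correlation (adjusted p = 0.79). It fell over Notch pathway and E(spl) complex (adjusted p = 0.0074; 2 of 20 lower adjusted over the list alone) and neuronal function (adjusted p = 0.0021; 1 of 39 lower adjusted over the list alone). With an estimated correlation the adjusted p of these 2 lists was 0.79. It fell as well over neuronal differentiation factors (adjusted p = 0.0049; 2 of 18 lower adjusted over the list alone) and Polycomb target developmental transcription factors (adjusted p = 0.00071). These 2 lists had adjusted p of 0.79 with an estimated correlation. Of the 62 Polycomb targets, 1 fell over all genes, and adjusted over the list alone 6 fell and 1 rose. Of these targets salm was at -2.77 ± 0.80 and Dll at 2.55 ± 0.75 (log2 fold change ± SE). HLHmbeta and HLHm7 of the E(spl) complex were at -2.15 ± 0.70 and -2.25 ± 0.79, and Appl and Cha among neuronal function genes at -2.65 ± 0.73 and -2.001 ± 0.77. The differentiation factors nerfin-1 and toy were at -2.22 ± 0.72 and -2.02 ± 0.70. Type I replicate 1 lay above replicate 2 at Appl (85.5 and 28.4 CPM), Cha (38.7 and 9.85) and nerfin-1 (58.4 and 17.8), where neurons were at 114 ± 74.3, 59.9 ± 22.5 and 104 ± 58.1 CPM. Cell cycle genes (adjusted p = 8.3e-05; 35 of 36 lower), Polycomb and Trithorax group members (adjusted p = 0.00012; 28 of 28 lower), growth (adjusted p = 0.021) and oxidative phosphorylation (adjusted p = 0.0074) also passed as lower, with no member called over all genes. None of these 4 lists passed with an estimated correlation (adjusted p = 0.79). The only growth list member called in another test was Thor, which the heat shock and stress response list also holds. It was higher, at 2.70 ± 0.72, adjusted over the growth list alone, in the fit of these groups alone (edgeR adjusted p = 0.0072) and with DESeq2. Muscle (adjusted p = 0.0074) and hemocyte and fat body markers (adjusted p = 0.027) passed as higher. Adjusted p was 0.79 for these 2 lists with an estimated correlation. With abundance-trend offsets these 2 lists, the 4 before them and neuroblast identity no longer passed, and oxidative phosphorylation changed sign (adjusted p = 0.94). Hemocyte and fat body markers did not pass with library totals either (adjusted p = 0.074). The type II lineage list did not pass (adjusted p = 0.55), with 2 of 14 members higher adjusted over the list alone. Of these genes Sp1 was at 79.3 ± 16.3 CPM in brat RNAi and 14.3 ± 1.2 in type I neuroblasts (log2 fold change 2.47, SE 0.74; edgeR adjusted p = 0.16, and 0.059 in the fit of these groups alone; DESeq2 adjusted p = 0.00044). Its neighbour btd was at 62.2 ± 10.8 and 17.4 ± 0.607 CPM (log2 fold change 1.84, SE 0.72; edgeR adjusted p = 0.66, and 0.43 in the fit of these groups alone; DESeq2 adjusted p = 0.036). In temporal patterning, which did not pass, lin-28 was at 2.42 ± 0.80 and Eip93F at -2.003 ± 0.76. The SBa code block called 4 higher and 14 lower in Polycomb targets, 1 higher and 5 lower in neuronal differentiation factors, 0 higher and 9 lower in neuronal function, 0 higher and 2 lower in neuroblast identity and 0 higher and 2 lower in Notch pathway. The other 6 lists did not pass; glycolysis and heat shock and stress response held ImpL3 and Gadd45, and 1 H99 gene and 1 glia marker were lower adjusted over the list alone.

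**Figure D2:**
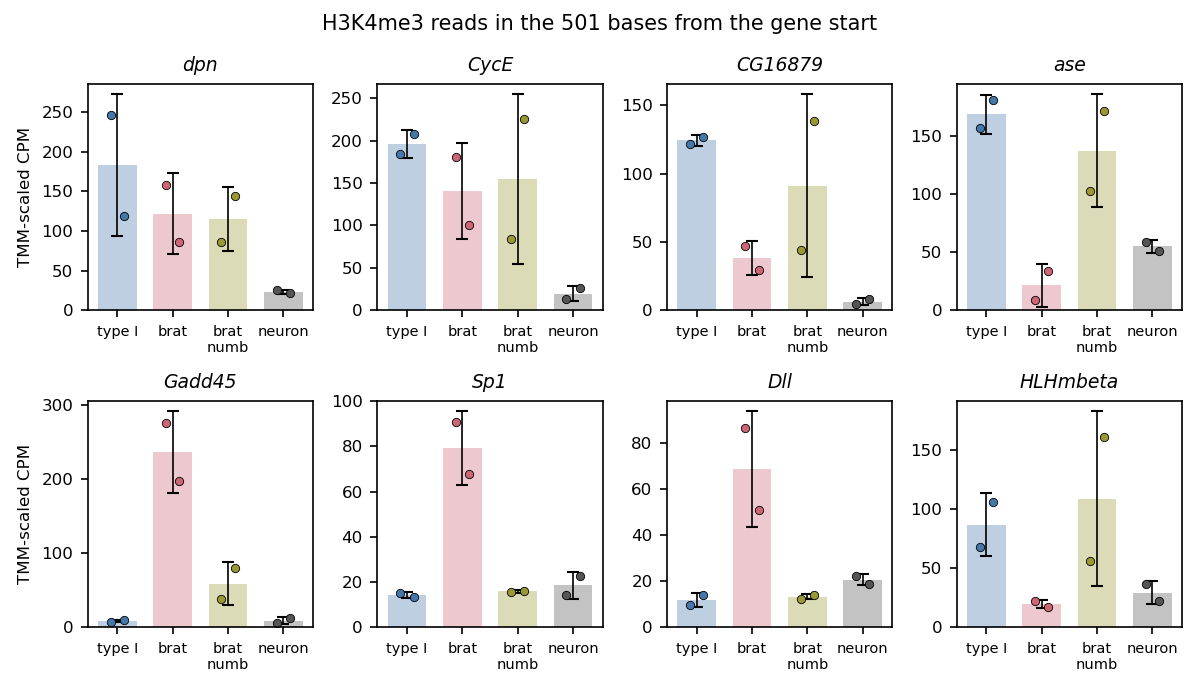
H3K4me3 at 8 gene starts in TMM-scaled CPM, by group; points are the 2 libraries, bars their mean and whiskers the SD. At ase, brat RNAi lies at 21.2 ± 18.1 CPM and type I neuroblasts at 168 ± 16.8; at Gadd45 and Sp1 brat RNAi lies above every other group.

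At btd and Sp1 H3K27me3 was lower in the brat RNAi libraries than in type I neuroblasts, though edgeR called no gene for this mark. At Sp1 (FBgn0020378, X: 9623681 to 9650237), a Krüppel-like factor gene active in type II lineages, it was 912 ± 319 CPM in type I neuroblasts, 77.5 ± 21.6 in brat RNAi and 743 ± 117 in brat numb RNAi (SD, n = 2). The neighbouring paralog btd (FBgn0000233, X: 9588221 to 9591606) was at 119 ± 50.7, 8.01 ± 0.423 and 92.8 ± 29.1 CPM. The log2 fold change of brat RNAi against type I was -3.56 ± 0.70 at Sp1 and -3.90 ± 0.78 at btd (SE), with an edgeR adjusted p of 0.62 for each. That fit of all 8 libraries also takes in the spread of the neuron libraries, which were at 1195 ± 1093 CPM at Sp1 and 135 ± 132 at btd. In the fit of these groups alone the adjusted p was 2.0e-10 and 2.6e-07, and with DESeq2 2.9e-06 and 2.0e-06. Within SBa code 26 the log2 ratio was -4.19 at Sp1 and -4.21 at btd. Chosen after their values were seen, the small genes CG42657, beside btd, and CR43498, between btd and Sp1, were at log2 fold changes of -3.59 and -4.15, while the flanking genes nej and CG1354 were at -0.11 and 0.03.

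**Figure D3:**
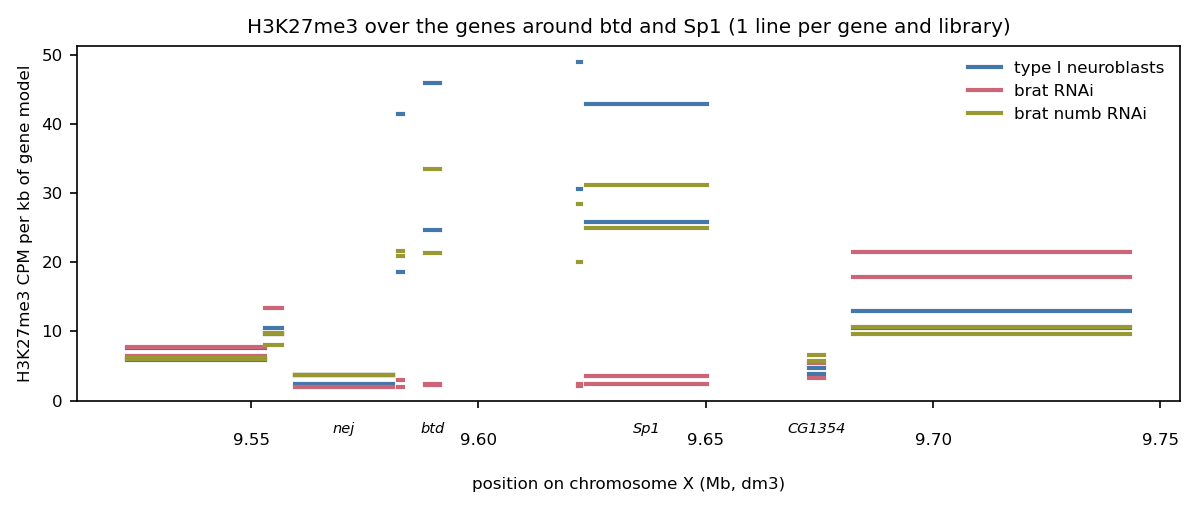
H3K27me3 around btd and Sp1 on chromosome X (dm3 position in Mb, horizontal axis), in TMM-scaled CPM per kb of gene model, with 1 line per gene and library. From CG42657 to Sp1 the brat RNAi lines lie below those of type I neuroblasts and brat numb RNAi, whereas at nej and CG1354 the lines lie close together.

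Other regulators, chosen after their values were seen, also had lower mean H3K27me3 in brat RNAi. H3K27me3 over pnt, an ETS factor of type II lineages (FBgn0003118, 3R: 19116826 to 19171884), was 1635 ± 616 CPM in type I neuroblasts and 426 ± 24.7 in brat RNAi (log2 fold change -1.94 ± 0.55, SE). The log2 fold change was -3.17 ± 0.70 at tll (FBgn0003720, 3R: 26678037 to 26680095), -3.12 ± 0.67 at Dll (FBgn0000157, 2R: 20702353 to 20722686) and -3.19 ± 0.73 at eya (FBgn0000320, 2L: 6527447 to 6546972). It was -2.71 ± 0.70 at so (FBgn0003460, 2R: 3306537 to 3322377), -2.13 ± 0.73 at Six4 (FBgn0027364, 3L: 20781986 to 20785868) and -1.94 ± 0.57 at the RNA-binding temporal gene Imp (FBgn0262735, X: 10682721 to 10716815). For these 7 genes the edgeR adjusted p was 0.62 to 0.75, and in the fit of these groups alone 1.0e-09 to 0.0012. DESeq2 did not call pnt, Six4 and Imp (adjusted p = 0.053, 0.1 and 0.064) and called the other 4 (7.2e-05 to 0.0043). H3K27me3 was higher in brat RNAi at ase (16.8 ± 2.97 to 44.8 ± 9.88 CPM; log2 fold change 1.42 ± 0.30, SE; edgeR adjusted p = 0.62, and 0.61 in the fit of these groups alone; DESeq2 adjusted p = 0.004). It was also higher at the ecdysone-induced gene Eip93F (351 ± 7.23 to 720 ± 114 CPM; 1.04 ± 0.18; edgeR adjusted p = 0.45, and 0.095 in the fit of these groups alone; DESeq2 adjusted p = 0.032). The smallest edgeR adjusted p, 0.11, belonged to Cyp6a17, a cytochrome P450 gene, at -3.73 ± 0.42; its adjusted p was 5.9e-06 in the fit of these groups alone and 6.1e-13 with DESeq2.

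As a list, type II lineage and intermediate progenitors fell in H3K27me3 (adjusted p = 1.5e-06). The list had adjusted p = 0.62 with an estimated correlation. The median log2 fold change was -0.41, with 3 of 14 members higher. Of its members 0 of 14 passed over all genes in edgeR, 5 were lower at an unadjusted p under 0.05, 4 were lower adjusted over the list alone, 6 in the fit of these groups alone and 3 with DESeq2. Cell cycle and DNA replication (adjusted p = 6.8e-08), oxidative phosphorylation (adjusted p = 4.6e-05) and heat shock and stress response (adjusted p = 0.00025; 2 lower adjusted over the list alone) also fell. These 3 lists had adjusted p of 0.23 to 0.62 with an estimated correlation. The cell cycle gene dpa was at 17.7 ± 4.84 CPM in type I neuroblasts and 11 ± 0.72 in brat RNAi. Whether such low levels exceed background was not tested. A fall was also found for growth (adjusted p = 0.00039), Polycomb and Trithorax group members (adjusted p = 0.0099) and glycolysis (adjusted p = 0.036; 1 lower adjusted over the list alone). None of these 3 lists passed with an estimated correlation (adjusted p = 0.62 to 0.65). The glycolysis gene ImpL3 was at -1.32 ± 0.32 and asparagine-synthetase at -1.77 ± 0.28 (log2 fold change ± SE); DESeq2 called both (adjusted p = 0.044 and 3.1e-05), and edgeR's fit of these groups alone called neither (adjusted p = 0.81 and 0.13). Neuronal function (adjusted p = 7.3e-05), muscle markers (adjusted p = 0.0023) and germline genes (adjusted p = 0.036) rose, with no member called. Adjusted p was 0.62 to 0.65 for these 3 lists with an estimated correlation. Among neuronal genes Sh and cac were at 0.74 ± 0.17 and 0.72 ± 0.21. Glycolysis, neuronal function and germline genes did not pass with abundance-trend offsets. Among the 9 other lists, which did not pass, 1 neuroblast identity gene was higher, and in temporal patterning 1 gene was higher and 1 lower, adjusted over the list alone. The gene mira was at -1.04 ± 0.42 and pros at 1.23 ± 0.35 (adjusted p = 0.017 in the fit of these groups alone and 0.23 with DESeq2). Of 14182 genes, edgeR called 0 (842 at an unadjusted p under 0.05), DESeq2 14 higher and 27 lower, and the fit of these groups alone 3 higher and 21 lower. Without neuron replicate 1 edgeR called 1 higher and 11 lower, and without neuron replicate 2 it called 0 higher and 14 lower.

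**Figure D4:**
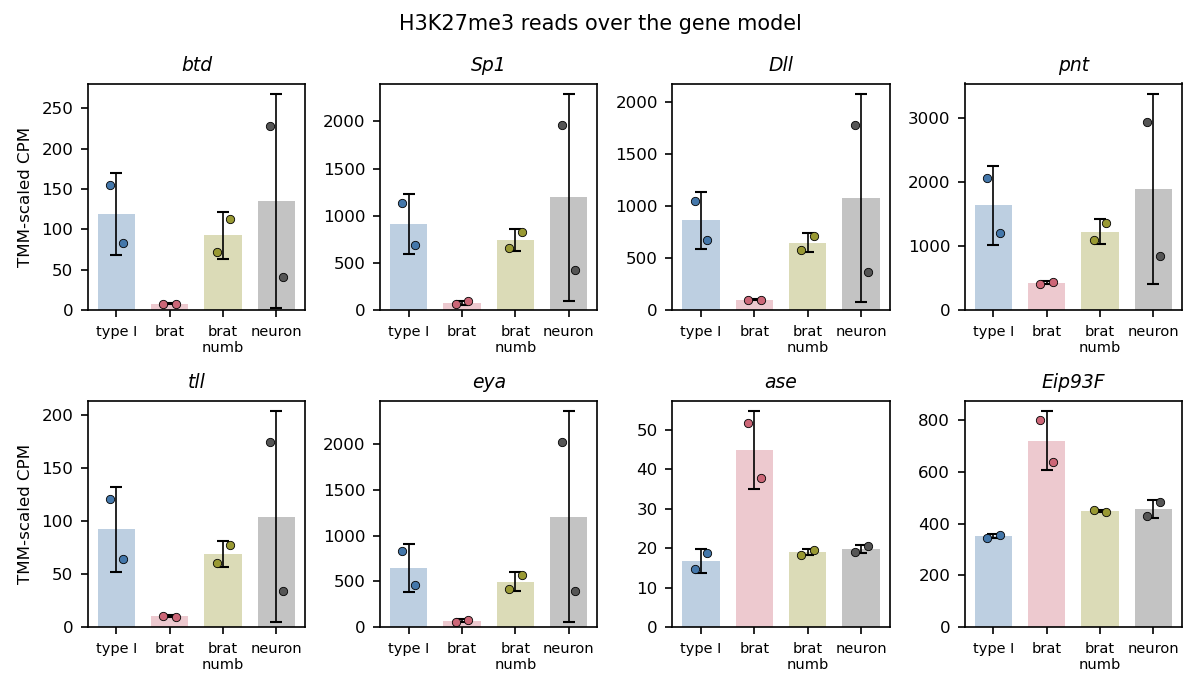
H3K27me3 over 8 gene models in TMM-scaled CPM, by group; points are the 2 libraries, bars their mean and whiskers the SD. The brat RNAi libraries lie lowest at btd, Sp1, Dll, pnt, tll and eya and highest at ase and Eip93F, and the neuron libraries lie far apart at the first 6.

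The marks moved in opposite directions at some of these genes. With DESeq2, 6 genes were higher in H3K4me3 and lower in H3K27me3 in brat RNAi where 0.09 were expected (1-sided Fisher's exact p = 3.0e-10): Sp1, btd, Dll, ImpL3, asparagine-synthetase and Nrx-1, named after their values were seen. The reverse held for ase and Eip93F, 2 genes where 0.07 were expected (1-sided Fisher's exact p = 0.0022). Sp1 and btd are neighbours whose H3K27me3 was lower together, yet Fisher's test counts them as independent. The edgeR calls overlapped at 0 genes, as H3K27me3 had no calls. Across genes the log2 fold changes of the marks correlated at r = 0.27, and at 0.03 with abundance-trend offsets. This r was 0.05 without type I replicate 2, 0.09 without brat RNAi replicate 1 and 0.11 without brat RNAi replicate 2.

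The brat numb RNAi neuroblasts were compared with type I neuroblasts with the same question. H3K4me3 was higher at asparagine-synthetase (114 ± 64.1 against 12.1 ± 0.279 CPM, SD, n = 2; log2 fold change 3.24, SE 0.73, adjusted p = 0.086, edgeR, and 0.00085 in the fit of these groups alone; DESeq2 adjusted p = 0.0079). It was higher at Gadd45 (58.9 ± 29.5 against 8.14 ± 1.55 CPM; log2 fold change 2.85, SE 0.72, adjusted p = 0.25, and 0.11 in the fit of these groups alone; DESeq2 adjusted p = 0.043). ImpL3 was at 2.496 ± 0.72 and Thor at 2.35 ± 0.71 (log2 fold change ± SE). At ase, Sp1 and btd the values were -0.30 ± 0.66, 0.14 ± 0.70 and 0.15 ± 0.71; these differ in sign between scalings. With the SBa code block the log2 fold changes were -1.99 at ase, 0.71 at Sp1 and 0.92 at btd, with edgeR adjusted p of 0.051, 0.77 and 0.68. Polycomb and Trithorax group members (adjusted p = 7.1e-07), cell cycle genes (adjusted p = 3.5e-06) and oxidative phosphorylation (adjusted p = 6.0e-06) fell as lists. With an estimated correlation the adjusted p of these 3 lists was 0.75. Growth (adjusted p = 0.00066) and neuronal function (adjusted p = 0.04) fell too, and hemocyte and fat body (adjusted p = 0.013) and muscle markers (adjusted p = 0.013) rose. These 4 lists had adjusted p of 0.75 with an estimated correlation. Of the 7 lists, neuronal function alone passed with abundance-trend offsets; it did not pass with library totals (adjusted p = 0.12). Its members Appl and Rab3 were at -2.28 ± 0.71 and -1.83 ± 0.70, and scrt of neuroblast identity was at -1.47 ± 0.69. The type I libraries stood apart at these 3 genes, replicate 1 above replicate 2 (85.5 and 28.4, 80.1 and 19.6 and 78.4 and 31.8 CPM), and neurons were at 114 ± 74.3, 138 ± 22.9 and 136 ± 48 CPM. The 12 other lists did not pass. Adjusted over the list alone, 2 heat shock and stress genes and 1 glycolysis gene were higher and 1 neuronal differentiation factor was lower. In growth, which fell as a list, 1 member was higher adjusted over the list alone. The code block called 9 neuronal function genes lower and 1 growth gene, Thor, higher.

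No gene passed in edgeR (463 of 14185 at an unadjusted p under 0.05; smallest adjusted p = 0.086). DESeq2 called 5 higher and 1 lower, library totals 4 higher, the fit of these groups alone 3 higher and 38 lower, and the SBa code block 127 higher and 219 lower; no code holds both groups. The count was 64 (0 higher, 64 lower) without type I replicate 2, 3 (3 higher, 0 lower) without brat RNAi replicate 2, 6 (4 higher, 2 lower) without brat numb RNAi replicate 1, 22 (4 higher, 18 lower) without neuron replicate 1 and 14 (4 higher, 10 lower) without neuron replicate 2. For H3K27me3, edgeR and DESeq2 called 0 of 14182 genes (420 at an unadjusted p under 0.05). H3K27me3 over Imp was 232 ± 35.3 CPM in brat numb RNAi and 703 ± 290 in type I neuroblasts (-1.60 ± 0.57), and over CG17838, the gene of the opposing temporal factor Syncrip, 315 ± 5.66 and 192 ± 55.9 CPM (0.72 ± 0.26). Sp1 and btd were at -0.30 ± 0.63 and -0.36 ± 0.69, Hml at -1.03 ± 0.26 and CG33523 at -1.39 ± 0.26, the last chosen after its values were seen. Neuronal function (adjusted p = 0.00075; 34 of 39 lower) and Polycomb target developmental transcription factors (adjusted p = 0.005; 61 of 62 lower) fell as lists, and Polycomb and Trithorax group members rose (adjusted p = 0.014). None of these 3 lists passed with an estimated correlation (adjusted p = 0.78). The falls did not pass with abundance-trend offsets (adjusted p = 0.79 and 0.66). The 16 other lists did not pass; 1 hemocyte gene was lower adjusted over the list alone. The marks correlated at r = -0.44 across genes, and at -0.03 with abundance-trend offsets, and no gene was called in both. Without brat numb RNAi replicate 1 the correlation was 0.01.

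Between the tumour types, brat numb RNAi against brat RNAi, the values at Sp1, Dll and ase lay the other way. H3K4me3 was 15.8 ± 0.455 CPM at Sp1 and 13.2 ± 1.12 at Dll in brat numb RNAi, against 79.3 ± 16.3 and 68.6 ± 25.2 in brat RNAi (SD, n = 2; log2 fold changes -2.33 ± 0.73 and -2.38 ± 0.74, SE). Their edgeR adjusted p was 1 each, in the fit of these groups alone 0.69 and 0.93, and with DESeq2 0.0017 and 0.0038. At ase it was 137 ± 48.5 against 21.2 ± 18.1 CPM (2.71 ± 0.71), and at scrt 1.98 ± 0.71. The Notch target genes HLHmbeta (FBgn0002733, 3R: 21831245 to 21831745) and E(spl) (FBgn0000591, 3R: 21865977 to 21866477) were at 109 ± 74 against 19.6 ± 3.58 CPM and 80.1 ± 57.7 against 16.9 ± 1.25 CPM (2.47 ± 0.71 and 2.24 ± 0.72). The Notch pathway and E(spl) complex list rose (adjusted p = 5.1e-11). This call was lost with an estimated correlation (adjusted p = 0.22). Its members had 0 of 20 past the threshold over all genes in edgeR's fit of all libraries or DESeq2, 3 higher adjusted over the list alone and 7 at an unadjusted p under 0.05. With the SBa code block, where this comparison rests on 1 library of each group, the log2 fold change was 3.24 at HLHmbeta and 2.91 at E(spl). Polycomb target developmental transcription factors rose (adjusted p = 9.7e-17), with 7 higher and 1 lower adjusted over the list alone. The list had adjusted p = 0.53 with an estimated correlation. Of them ems was at 3.31 ± 0.85. Neuroblast identity (adjusted p = 0.0022; 2 higher adjusted over the list alone), temporal patterning (adjusted p = 0.0036) and neuronal differentiation factors (adjusted p = 0.011) rose as well. These 3 lists had adjusted p of 0.53 to 0.58 with an estimated correlation. Hox genes (adjusted p = 0.014), of which Antp was at 1.97 ± 0.75, glia markers (adjusted p = 0.011) and germline genes (adjusted p = 0.022) rose. None of these 3 lists passed with an estimated correlation (adjusted p = 0.59 to 0.61). Heat shock genes (adjusted p = 0.044) and H99 genes (adjusted p = 0.049) rose, while oxidative phosphorylation (adjusted p = 0.0062) and growth (adjusted p = 0.049) fell. Adjusted p was 0.57 to 0.79 for these 4 lists with an estimated correlation. None of the last 7 lists passed with abundance-trend offsets, and of them oxidative phosphorylation alone passed with library totals. The code block called 17 higher and 5 lower in Polycomb targets, 6 higher and 0 lower in neuroblast identity, 2 higher and 0 lower in temporal patterning and 7 higher and 3 lower in heat shock genes. For lists whose direction it did not share, it called 7 higher and 1 lower in growth, 2 higher and 1 lower in oxidative phosphorylation, 0 higher and 3 lower in glia markers, 1 higher and 2 lower in neuronal differentiation factors and 0 higher and 1 lower in Hox genes. The other 7 lists did not pass. The type II list was among them (adjusted p = 0.54; 8 of 14 higher, median log2 fold change 0.51), with 1 higher and 2 lower adjusted over the list alone.

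No gene passed in edgeR (215 of 14185 at an unadjusted p under 0.05; smallest adjusted p = 0.097, for CG30419 at 3.43 ± 0.78 and CG18278 at -3.74 ± 0.86, chosen after their values were seen). DESeq2 called 6 higher and 5 lower, library totals 2 higher, DESeq2 size factors 1 lower, the fit of these groups alone 11 lower, and the SBa code block 1724 higher and 2091 lower. Within code 68 the log2 ratio was -2.05 at Sp1, -1.84 at Dll, 2.32 at ase, 3.22 at HLHmbeta and 2.89 at E(spl). The count was 7 (1 higher, 6 lower) without type I replicate 1, 8 (1 higher, 7 lower) without type I replicate 2, 1 (1 higher, 0 lower) without brat RNAi replicate 2, 1 (1 higher, 0 lower) without brat numb RNAi replicate 1 and 2 (1 higher, 1 lower) without neuron replicate 2.

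H3K27me3 over the same loci was higher in brat numb RNAi than in brat RNAi: the log2 fold change was 3.26 ± 0.69 at Sp1, 3.54 ± 0.77 at btd, 2.75 ± 0.69 at tll, 2.71 ± 0.66 at Dll and 2.81 ± 0.72 at eya (SE). The edgeR adjusted p was 0.20 for each and 0.084 to 0.098 in the fit of these groups alone. The DESeq2 adjusted p was 1.1e-05 at Sp1, 0.00093 at Dll and 0.00094 at eya, with none given at btd and tll. It was lower at ase (-1.24 ± 0.30), Eip93F (-0.68 ± 0.18) and pros (-1.34 ± 0.35; edgeR adjusted p = 0.2, and 0.15 in the fit of these groups alone; DESeq2 adjusted p = 0.039). Within code 68 the log2 ratio was 3.15 at Sp1, 3.86 at btd and -0.95 at ase. Neuronal function (adjusted p = 2.0e-07) and muscle markers (adjusted p = 0.00075; 6 of 13 lower adjusted over the list alone) fell as lists. With an estimated correlation the adjusted p of these 2 lists was 0.6. Neuronal function had 16 of 39 lower adjusted over the list alone and 3 by DESeq2. The potassium channel gene Sh was at -0.97 ± 0.17 and the GABA receptor gene Rdl at -0.91 ± 0.18. Cell cycle genes rose (adjusted p = 2.0e-07; 36 of 36 higher), with dpa and Orc1 at 1.15 ± 0.33 and 1.19 ± 0.35. With an estimated correlation this list did not pass (adjusted p = 0.6). Levels were low: dpa was at 11 ± 0.72 CPM in brat RNAi and 24.4 ± 0.767 in brat numb RNAi, and Orc1 at 10.3 ± 0.404 and 23.5 ± 1.27. The gene btd, of like length, was at 92.8 ± 29.1 CPM in brat numb RNAi. Whether such low levels exceed background was not tested, as no input was used. Lists that rose as well were Polycomb and Trithorax group members (adjusted p = 0.00055), growth (adjusted p = 0.00059), oxidative phosphorylation (adjusted p = 0.0015), heat shock (adjusted p = 0.0094) and glycolysis (adjusted p = 0.021). None of these 5 lists passed with an estimated correlation (adjusted p = 0.56 to 0.6). Neuronal function and heat shock did not pass with abundance-trend offsets. The type II list was at adjusted p = 0.051, with 3 of 14 higher adjusted over the list alone. The 10 other lists did not pass; adjusted over the list alone, temporal patterning and neuronal differentiation factors each had 1 higher and 1 lower, and neuroblast identity and germline genes each 1 lower. Of 14182 genes edgeR called 0 (2660 at an unadjusted p under 0.05). DESeq2 called 4 higher and 88 lower among the genes to which it gave an adjusted p, which leave out btd, tll, ase, dpa and Orc1. Genes without an adjusted p counted as not called in the overlap of the marks. Without neuron replicate 1 edgeR called 7 higher and 4 lower, and without neuron replicate 2 it called 8 and 2. With DESeq2, Dll and Sp1 were lower in H3K4me3 and higher in H3K27me3 (1-sided Fisher's exact p = 6.0e-07); the marks correlated at r = -0.08 across genes, and at 0.09 with abundance-trend offsets. The correlation was 0.23 without brat RNAi replicate 1, -0.46 without brat RNAi replicate 2, 0.52 without brat numb RNAi replicate 1 and -0.54 without brat numb RNAi replicate 2. It was -0.15 without either neuron replicate 1 or neuron replicate 2.

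Changes shared by the tumour types were measured against simulated libraries in which neither type differs from type I neuroblasts, because both are compared with the same 2 type I libraries. The simulation ignores SBa codes, although brat RNAi replicate 2 and brat numb RNAi replicate 2 share code 68, and replicate 1 of type I and of brat RNAi share code 27 (26 for H3K27me3). A covariance from shared codes was therefore not separated from 1 of the tumour types. Across genes the H3K4me3 log2 fold changes of brat RNAi and brat numb RNAi had a covariance of 0.562 (r = 0.79), against 0.274 (SD 0.00496 over 20 draws; r = 0.49) in the simulation. With abundance-trend offsets the covariance was 0.203, below the simulated 0.293. The excess over the simulation also rested on single libraries. With the same library left out of the simulation, the H3K4me3 covariance was 0.340 against 0.592 without type I replicate 1, and 0.203 against 0.275 without brat numb RNAi replicate 1. It was 0.293 against 0.273 without brat RNAi replicate 2. It was 1.096 against 0.604 without type I replicate 2, 0.823 against 0.274 without brat RNAi replicate 1 and 0.869 against 0.273 without brat numb RNAi replicate 2. An excess shared by the tumour types therefore did not hold across libraries. For H3K27me3 the covariance was -0.00766 (r = -0.05), below the simulated 0.0836 (r = 0.50). For both marks the simulation gave all groups the same spread at a gene. H3K27me3 chi-square per degree of freedom was 269 between neuron libraries and 37.3 between those of type I neuroblasts. The simulated covariance depends on the spread given to the type I libraries and may be too high, so no conclusion is drawn from values below it. The H3K27me3 covariance was 0.00718 without type I replicate 1, 0.113 without type I replicate 2, 0.0534 without brat RNAi replicate 1 and -0.0756 without brat RNAi replicate 2, each below its simulated value (0.171, 0.173, 0.0836 and 0.0837). No gene was called in the same direction in both types by edgeR for either mark; for H3K4me3 DESeq2 called 5 higher and 1 lower, and library totals 4 higher.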

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

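The tests that combined abundance-trend offsets with a block, crossed the replicate numbers, combined the 2-group fit with the SBa code, left out the 2 shallowest libraries or took opposite marks at an unadjusted p under 0.05 were chosen after the results were seen. All values are counts of genes past an adjusted p of 0.05 unless stated, and the cause was not tested where a value moved. H3K4me3 libraries held 2461222 to 12258131 reads, and chi-square per degree of freedom between libraries of a group was 36.5 to 74.9 for this mark, so the spread exceeded counting error; whether depth limits the calls was not tested. On simulated data edgeR recovered 0 of 56 genes changed 2-fold, 12 of 73 changed 4-fold and 32 of 71 changed 8-fold for H3K4me3. For H3K27me3 it recovered 5 of 56, 60 of 73 and 71 of 71. It made 2 and 8 calls among unchanged genes, and DESeq2 31 and 42. The simulation gave all groups the same spread, whereas H3K27me3 chi-square per degree of freedom was 269 between neuron libraries and 10.1 between those of brat numb RNAi. Recovery there thus does not give the power in these data: H3K27me3 over Sp1 in brat RNAi, at -3.56 ± 0.70, had an edgeR adjusted p of 0.62. Without 1 library its group holds 1, which is assumed to vary like the other groups. Dropping the low-count filter left every gene count as it was. The SBa code block could not be fitted for H3K27me3, which leaves no residual degrees of freedom. Of the 14284 genes listed, 152 share the coordinates of an earlier gene for H3K4me3 and 118 for H3K27me3. A fit with each distinct window counted once was not run, so the effect of repeated windows was not tested.

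Against type I neuroblasts, unless another group is named, edgeR called 64 genes for H3K4me3 in neurons, 14 in brat RNAi, 0 in brat numb RNAi and 0 between brat numb RNAi and brat RNAi. DESeq2 size factors gave 19 for neurons (1 higher, 18 lower), 23 for brat RNAi (11 higher, 12 lower) and 1 for brat numb RNAi against brat RNAi (0 higher, 1 lower). Library totals gave 472 for neurons (99 higher, 373 lower), 45 for brat RNAi (12 higher, 33 lower), 4 for brat numb RNAi (4 higher, 0 lower) and 2 for brat numb RNAi against brat RNAi (2 higher, 0 lower). Abundance-trend offsets gave 2 for brat RNAi (2 higher, 0 lower). The DESeq2 test gave 376 for neurons (13 higher, 363 lower), 120 for brat RNAi (48 higher, 72 lower), 6 for brat numb RNAi (5 higher, 1 lower) and 11 for brat numb RNAi against brat RNAi (6 higher, 5 lower). The fit of only the 2 groups compared gave 489 for neurons (63 higher, 426 lower), 41 for brat numb RNAi (3 higher, 38 lower) and 11 for brat numb RNAi against brat RNAi (0 higher, 11 lower). The SBa code block gave 4611 for neurons (2313 higher, 2298 lower), 572 for brat RNAi (244 higher, 328 lower), 346 for brat numb RNAi (127 higher, 219 lower) and 3815 for brat numb RNAi against brat RNAi (1724 higher, 2091 lower). Abundance-trend offsets with the SBa code block gave 2403 for neurons (1243 higher, 1160 lower), 463 for brat RNAi (119 higher, 344 lower), 297 for brat numb RNAi (105 higher, 192 lower) and 1470 for brat numb RNAi against brat RNAi (757 higher, 713 lower). The 2-group fit with the SBa code block gave 4661 for neurons (2401 higher, 2260 lower). Leaving out the 2 shallowest libraries gave 522 for neurons (35 higher, 487 lower), 8 for brat numb RNAi (4 higher, 4 lower) and 1 for brat numb RNAi against brat RNAi (1 higher, 0 lower). It left 13 for brat RNAi (5 higher, 8 lower), of which 4 were among the 14. For H3K27me3, where edgeR called 0 genes in every comparison, the DESeq2 test gave 52 for neurons (43 higher, 9 lower), 41 for brat RNAi (14 higher, 27 lower) and 92 for brat numb RNAi against brat RNAi (4 higher, 88 lower). The 2-group fit gave 11 for neurons (7 higher, 4 lower) and 24 for brat RNAi (3 higher, 21 lower). Offsets and scalings of H3K27me3 alone gave 0.

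Replicate numbers did not pair the libraries in every group: deviations from the group means of libraries with the same number correlated at 0.74 between type I neuroblasts and neurons and -0.62 between brat RNAi and brat numb RNAi for H3K4me3, and at 0.61 and -0.41 for H3K27me3. With the replicate number as a block, H3K4me3 had 33 for neurons (3 higher, 30 lower), 31 for brat RNAi (19 higher, 12 lower) and 2 for brat numb RNAi against brat RNAi (1 higher, 1 lower), and H3K27me3 3 for neurons (0 higher, 3 lower), 1 for brat RNAi (0 higher, 1 lower) and 94 for brat numb RNAi against brat RNAi (11 higher, 83 lower). With abundance-trend offsets as well, the block gave 2 for brat RNAi (2 higher, 0 lower) for H3K4me3 and 1 for brat RNAi (0 higher, 1 lower) for H3K27me3. Of the 64 genes called in neurons for H3K4me3 the replicate block kept 28, and of the 14 in brat RNAi 13. In a crossed block the numbers of brat numb RNAi alone were exchanged, because its deviations ran against those of the other groups. The exchange was thus fitted to these same libraries, and the larger counts it gave are no separate evidence of differences. Crossing the pairing of the block gave 1611 for neurons (362 higher, 1249 lower), 980 for brat RNAi (459 higher, 521 lower), 1274 for brat numb RNAi (300 higher, 974 lower) and 48 for brat numb RNAi against brat RNAi (29 higher, 19 lower) for H3K4me3, and 60 for neurons (25 higher, 35 lower), 25 for brat RNAi (12 higher, 13 lower), 1 for brat numb RNAi (0 higher, 1 lower) and 1577 for brat numb RNAi against brat RNAi (732 higher, 845 lower) for H3K27me3.

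Opposite changes of the marks, 0 with edgeR, numbered 9, 8 and 2 with the DESeq2 test for neurons, brat RNAi and brat numb RNAi against brat RNAi. At an unadjusted p under 0.05 they numbered 100, 66, 12 and 30 in the order of the comparisons. H3K4me3 changes shared by the tumour types, 0 with edgeR, numbered 4 with library totals and 6 with the DESeq2 test. Their covariance less the simulated one was 0.288 and reversed to -0.09 with abundance-trend offsets. Leaving out each library in turn, also from the simulation, it ran from -0.252 (without type I replicate 1) to 0.597 (without brat numb RNAi replicate 2), and was -0.0723 without brat numb RNAi replicate 1 and 0.0199 without brat RNAi replicate 2. The reference simulated without the same library was chosen after the results were seen. Of 152 list tests 61 passed: of these 32 passed with abundance-trend offsets, 53 with library totals, 60 with DESeq2 size factors, 61 with the replicate block and 0 with an estimated correlation. The H3K4me3 oxidative phosphorylation list reversed in brat RNAi with abundance-trend offsets (adjusted p = 0.94). Of 24 genes named by the rule past the threshold, 11 passed with abundance-trend offsets.

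Log2 fold changes of genes not past the threshold reversed as follows. With library totals only they were 0.10 at brat (H3K4me3, neurons), 0.56 at numb (H3K4me3, brat numb RNAi), 0.16 at ase (H3K4me3, brat numb RNAi), 0.0456 at numb (H3K27me3, brat numb RNAi), 0.17 at brat (H3K27me3, brat numb RNAi against brat RNAi), 0.29 at numb (H3K27me3, brat numb RNAi against brat RNAi). With abundance-trend offsets they were 0.0149 at brat (H3K4me3, neurons), 0.0496 at brat (H3K4me3, brat RNAi), 0.0457 at brat (H3K4me3, brat numb RNAi), 0.0512 at ase (H3K4me3, brat numb RNAi), -0.15 at Sp1 (H3K4me3, brat numb RNAi), -0.0724 at btd (H3K4me3, brat numb RNAi), 0.0432 at numb (H3K27me3, brat numb RNAi), 0.00968 at Sp1 (H3K27me3, brat numb RNAi), 0.20 at brat (H3K27me3, brat numb RNAi against brat RNAi), 0.29 at numb (H3K27me3, brat numb RNAi against brat RNAi). With SBa code block they were -0.44 at numb (H3K4me3, brat RNAi), 1.15 at scrt (H3K4me3, brat numb RNAi), 0.15 at brat (H3K4me3, brat numb RNAi against brat RNAi). With only the 2 groups compared they were 0.15 at numb (H3K4me3, brat numb RNAi). With DESeq2 size factors they were -0.078 at Sp1 (H3K4me3, brat numb RNAi), -0.0506 at btd (H3K4me3, brat numb RNAi). With DESeq2 test they were -0.0753 at Sp1 (H3K4me3, brat numb RNAi), -0.0486 at btd (H3K4me3, brat numb RNAi).

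Leaving out each library in turn, H3K4me3 counts ran from 2 (without type I replicate 2) to 400 (without brat numb RNAi replicate 1) for neurons, 0 (without type I replicate 1) to 53 (without brat numb RNAi replicate 2) for brat RNAi, 0 (without type I replicate 1) to 64 (without type I replicate 2) for brat numb RNAi, 0 (without brat RNAi replicate 1) to 8 (without type I replicate 2) for brat numb RNAi against brat RNAi. H3K27me3 counts ran from 0 to 130 (without neuron replicate 2) for neurons, 0 to 14 (without neuron replicate 2) for brat RNAi, 0 to 0 for brat numb RNAi, 0 to 11 (without neuron replicate 1) for brat numb RNAi against brat RNAi. Opposite marks ran from 0 to 9 (without neuron replicate 2) for neurons and were 0 for the other comparisons, where edgeR with all libraries also gave 0. Shared H3K4me3 changes ran from 0 (without type I replicate 1) to 9 (without type I replicate 2), shared H3K27me3 changes were 0, and genes named by the rule that passed ran from 5 (without type I replicate 1) to 24 (without brat numb RNAi replicate 2). Values that reversed ran from -0.56 to 0.19 at brat (H3K4me3, neurons), -0.0918 to 1.45 at numb (H3K4me3, brat RNAi), -0.62 to 0.80 at numb (H3K4me3, brat numb RNAi), -0.72 to 0.0162 at ase (H3K4me3, brat numb RNAi), -0.071 to 0.33 at btd (H3K4me3, brat numb RNAi), -1.18 to 0.24 at numb (H3K4me3, brat numb RNAi against brat RNAi), -0.52 to 0.22 at brat (H3K27me3, brat RNAi), -0.38 to 0.0934 at numb (H3K27me3, brat RNAi), -0.61 to 0.14 at Sp1 (H3K27me3, brat numb RNAi), -0.74 to 0.18 at btd (H3K27me3, brat numb RNAi), -0.41 to 0.33 at brat (H3K27me3, brat numb RNAi against brat RNAi), -0.19 to 0.28 at numb (H3K27me3, brat numb RNAi against brat RNAi).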

Other observations

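Tests of explanations in this part were all chosen after the results were seen. The RNA-binding genes Imp and CG17838 (Syncrip) mark early and late neuroblast age. H3K27me3 over Imp (FBgn0262735) was 908.1 and 497.4 CPM in the type I libraries, 148.5 and 218.8 in brat RNAi, 257.1 and 207.1 in brat numb RNAi, and 1220 and 361.5 in neurons. Over CG17838 (FBgn0038826) it was 152.5 and 231.5, 235 and 306.1, 311.4 and 319.4, and 277 and 395.2 CPM in the same order. H3K4me3 at the start of Imp was 9.943 and 3.995 CPM in type I libraries and 6.284 and 11.24 in brat RNAi. Neither gene passed edgeR's test of all 8 libraries for either mark in any comparison (lowest adjusted p = 0.5267, for H3K27me3 over CG17838 in neurons), but Imp passed for H3K27me3 in brat RNAi in the fit of brat RNAi and type I alone (adjusted p = 5.5e-05).

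H3K27me3 was lower over btd, Sp1, tll, pnt, Six4, Dll, eya and so in brat RNAi than in type I neuroblasts, by log2 fold changes of -1.94 to -3.90. These 8 genes were chosen after their values in these libraries were seen. Weaker enrichment in the brat RNAi libraries would lower other Polycomb targets alike, but the lower quartile of the 59 others was -0.41 (median -0.15, upper quartile 0.09). A difference between SBa codes would leave no fall within a code. The ratio to type I within code 26 had a least negative value of -2.29, at Six4. That of brat RNAi to brat numb RNAi within code 68 was at most -1.62, at pnt. Each ratio compares 1 library with 1 and uses the brat RNAi libraries in which the genes had been chosen, so the ratios are no independent test. Loss of the DNA of these loci would lower H3K4me3, whose median change at the 8 genes was 1.58 (quartiles 0.96 and 2.24). No biological explanation was tested.

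H3K4me3 on chromosome 4 differed between libraries of 1 group, by 3.34 between the type I libraries on the log2 scale. The 3 libraries of SBa code 27 lay above the other 5, the lowest of them by 0.92. Depth is argued against by the 5 libraries outside code 27, which hold the deepest and the shallowest and spanned 0.57 of a range of 3.96. Within code 27 the libraries of type I neuroblasts, brat RNAi and neurons spanned 2.47, so a difference between cell groups within the code cannot be told apart from 1 between single libraries. A difference between library batches may explain the pattern; what the code stands for is not stated.

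H3K4me3 was higher at Notch pathway and E(spl) genes in brat numb RNAi than in brat RNAi neuroblasts, with a median log2 fold change of 1.03 over 20 genes. Of 10000 random lists matched on abundance in 20 bins, 0% had a median as high, which argues against a shift of all genes of like abundance, though random genes lack the correlation within the E(spl) complex and the list did not pass with an estimated correlation (adjusted p = 0.22). Within SBa code 68 the median of the list less that of all genes was 0.80 (lower quartile 0.26). Of its 20 members 16 lay above, so the rise was also present within 1 code. This ratio compares 1 library with 1, of 11141538 and 2461222 reads, and both belong to those in which the pattern was seen. It is therefore no independent test of a difference between codes, and lists matched on abundance were not drawn within the code. Loss of Numb could raise these marks above the type I level, but against type I neuroblasts the list, with a median of 0.50 and 14 of 20 members higher, had adjusted p = 0.1881; in brat RNAi it fell against type I (median -0.47, 16 of 20 lower, adjusted p = 0.0074, and 0.79 with an estimated correlation). Whether they are raised by loss of Numb or lowered in brat RNAi cannot be told apart, because no group had numb RNAi alone. A difference in lineage between the RNAi groups cannot be told apart either, because no group held normal type II neuroblasts.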
